A study of Mus musculus with 74 samples.

How the data were processed

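RNA was sequenced from mouse cells, and the deposited files hold 1 expression value per gene and library. According to the submitters' notes, reads were aligned with Bowtie2 2.0 to mm10 (GRCm38) and quantified with RSEM. The authors deposited the values as normalized tag counts, a unit recorded here as a score, because they are neither raw counts nor a standard per-million unit. There were 2 tables, normalized apart from each other. The first, of the NSC-medium experiment, held 21241 genes in 54 libraries. The other, of the parallel experiment, held 20558 genes in 26 libraries. All values were whole numbers, and within a table every column had the same highest value (78139 and 87546) and nearly the same median (166 and 195, but 32 in 1 library of the first table and 194 in 2 of the other). Such columns are what full quantile normalization gives. Read depth is therefore unknown, and no interval or detection limit that needs it is given. A value of 0 is written as "listed at 0".

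Column sums other than that of the doubted library ran from 17698392 to 17710071 in the NSC-medium table and from 17848683 to 17866021 in the parallel table, which reflects the normalization. Genes at 0 made up 9.56% to 14.8% and 6.64% to 12.2% of the columns. The correlation between replicates on the log2 scale was 0.949 to 0.961 and 0.937 to 0.955, and 45 of 54 and 23 of 26 libraries were closest to their own replicate. BKM_Sox2 day 24 replicate 1 was the exception, with a column sum of 15873664, a median of 32, 24.5% of genes at 0 and a correlation of 0.0578 with its replicate. It is called the doubted library. Of its 21241 genes 18322 lie on the longest sequence of values that never falls along the rows of the file, against at most 4569 in any other library, a count made after the data were seen. It was kept in the fits as designed, because no exclusion had been planned, and the values without it are given beside. Within bins of genes by GC content, medians of the other libraries lay close together (175.5 to 206 in the bin of highest GC content in the NSC-medium table, 190.5 to 231.5 in the parallel table). In the doubted library they fell with GC content, from 150 in the lowest bin to 6, 6 and 7 in the 3 highest.

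Groups were taken from the sample labels. The columns of primary neural stem cells could be matched to their group only, so their replicate numbers are those of the columns. A further 4 columns could not be matched to a labelled sample and were not used. The labels do not say whether replicates were separate cultures, so each p measures only the spread between these libraries. The libraries of days 4 to 18 were named in another style than those of days 24 and 30, so a batch between these periods, if there was one, cannot be separated from the day, and no cocktail was tested across that boundary.

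Values were compared as log2 of the value plus 2, for genes with a value of at least 10 in at least 2 libraries (21133 and 20468 genes). One model with a mean for each group was fitted per table with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, and 20 contrasts were tested two-sided. A comparison over several days averaged the differences within each day, and the 3 interaction contrasts tested a difference between differences. P values were adjusted by the method of Benjamini and Hochberg within each contrast. A gene was called when its adjusted p was below 0.05 and its absolute log2 fold change was at least 1 (2-fold). "Rose" and "fell" are used of called genes. Fold changes are printed as log2 ± standard error, and levels as mean ± SD of the libraries of a group. For comparisons over several groups or days the levels are means of the group means on each side. No fold change is given against a group listed at 0.

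The comparisons, tests, thresholds, gene lists and the rule for naming genes were fixed before the data were examined. The 24 lists hold 372 genes, taken from general knowledge of markers and pathways: neural stem cell, neuron, astrocyte, oligodendrocyte, neural crest and Schwann, forebrain and midbrain, Hox, fibroblast, epithelial, keratinocyte, endothelial, endoderm, trophoblast, skeletal muscle, macrophage and blood, naive pluripotency, formative and primed pluripotency, cell cycle, senescence and p53, interferon response, ERK feedback, STAT3 targets, canonical Wnt targets, and the factor genes. Some genes stand in more than 1 list, such as Sox2, Sox3, Otx2, Cldn6, Cdx2, Sox10 and Ier3. Each list with at least 4 tested members was tested with camera from limma, which compares its genes with all others, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. The rule for genes named in the text was: in each contrast the 6 largest increases and 6 largest decreases among called genes whose libraries did not overlap at any day compared and whose mean reached 100 in a group; in each list described up to 4 called members with the largest changes and up to 2 uncalled members with the highest means; and always Sox2, Sox17, Pou3f4 (the gene of Brn4), Klf4, Myc, Nes, Olig2, Pou5f1, Nanog and Cdh1. Overlap was not checked in the interaction contrasts. Of the 186 genes with the largest changes, 64 (34.4%) were in the 10% of genes with the lowest GC content (up to 39.8%).

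The position of a library between MEFs (0) and primary neural stem cells (1) was the median, over the genes called higher (gain) or lower (loss) in neural stem cells, of its distance from MEFs divided by the distance between both cell types. Positions of cocktails were compared by a two-sided exact permutation of labels within days, adjusted over 6 tests on Dox and 6 after it. The method was tested on simulated data with the measured group means and spreads, in which 200 genes were given a log2 change of 2 or 1. Every simulated library was given the pooled spread of each gene, and genes were drawn independently of each other. In the NSC-medium table the spread of the doubted library was thus shared by all libraries. The shares called may therefore differ from those in the real fits. With all libraries in the spread, 16% to 75% of changes of 2 and 2% to 37% of changes of 1 were called. In the NSC-medium table without the doubted library these were 53% to 88% and 31% to 40%, and at most 6 unchanged genes were called in any run.

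Alternatives covered the pseudocount (0.5 and 8), no filter or a value of at least 50, rescaling by the median of ratios, another quantile normalization, the replicate number as a block, a fit to the compared groups alone, leaving out each library in turn, and for positions a log2 threshold of 3 or a mean limited to -1 to 2. Leaving out the doubted library from every fit was added after the data were seen. Methods for raw counts were not used, since the values are not raw counts. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

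Genes are identified by the symbol and Ensembl identifier in the files. Coordinates on GRCm38 are given for the genes that the text returns to most. Sox2 (ENSMUSG00000074637) lies on chromosome 3 from 34650405 to 34652461, Sox17 (ENSMUSG00000025902) on chromosome 1 from 4490931 to 4497354, Pou3f4 (ENSMUSG00000056854) on chromosome X from 110814280 to 110817207, Klf4 (ENSMUSG00000003032) on chromosome 4 from 55527143 to 55532466 and Myc (ENSMUSG00000022346) on chromosome 15 from 61985391 to 61990374. Pou5f1 (ENSMUSG00000024406) lies on chromosome 17 from 35506018 to 35510772, Nanog (ENSMUSG00000012396) on chromosome 6 from 122707489 to 122714633, Olig2 (ENSMUSG00000039830) on chromosome 16 from 91225457 to 91228677, Nes (ENSMUSG00000004891) on chromosome 3 from 87971078 to 87980451 and Cdh1 (ENSMUSG00000000303) on chromosome 8 from 106603351 to 106670246.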

Results

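The study followed mouse embryonic fibroblasts (MEFs) that carried a Sox2-GFP reporter and Dox-inducible lentiviral factors. Of the 4 cocktails in NSC medium (neural stem cell medium with bFGF and EGF), BKM_Sox2, BKM_Sox17 and BKM_FNV combined Brn4, Klf4 and c-Myc with Sox2, Sox17 or the engineered Sox17 variant eSox17FNV, and K_FNV held Klf4 and eSox17FNV alone. Cells were collected at days 4, 8, 12 and 18 with Dox and at days 24 and 30 after its withdrawal. Each group had 2 libraries, except for 1 library each of BKM_Sox17 and BKM_Sox2 at day 30, whose values have no SD. MEFs, primary neural stem cells (NSCs) and the established induced lines iNSC_KF and iNSC_BKMF had 2 libraries each. In a parallel experiment, MEFs with Klf4, c-Myc and eSox17FNV were held in N2B27 medium to day 8 and then moved to NSC medium or to LIF/2i, a pluripotency medium of LIF with a GSK3 and a MEK inhibitor. They were collected at days 12 and 16 with Dox and at days 20 and 24 without it, again with 2 libraries per group. Values are normalized tag counts whose read depth is unknown. For the called genes named here, no library of one group overlapped those of the other at any day compared unless stated, so the direction held in every library. This does not cover the interaction contrasts, where overlap was not checked. Counts of called genes in the NSC-medium table depended on the doubted library, BKM_Sox2 day 24 replicate 1, which widened the spread estimated for all groups, and the count without it follows each count.

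The first comparison asked how the starting and target cell types differed. NSCs expressed the neural progenitor genes that MEFs lacked: of 26 neural stem cell genes, 23 rose, 2 fell and 1 was not called. Olig2 stood at 15651 ± 905, Sox3 at 8459.5 ± 105 and Sox2 at 3448 ± 276 (n = 2), and all 3 were listed at 0 in MEFs. Nes, which fibroblasts also make, rose less (log2 2.53 ± 0.94, adjusted p = 0.0442), and its call ended after rescaling (adjusted p = 0.0559) or without any 1 of the 4 compared libraries (adjusted p = 0.113 to 0.181). Of 28 fibroblast genes 24 fell and 1 rose, among them Col1a2 (13 ± 18.4 against 44402 ± 0 in MEFs, log2 -12.53 ± 0.53) and Postn (16288 ± 0 in MEFs, listed at 0 in NSCs). Hox genes, which mark the trunk in the body axis, fell in 30 of 37 cases and rose in 2. Macrophage and blood genes fell in 11 of 12 cases, with Csf1r at 368 ± 53 in MEFs and 0 in NSCs. In total 4929 genes were called, 2378 higher and 2551 lower in NSCs, and 7165 without the doubted library. The list tests gave adjusted p = 6.1e-21 for neural stem cell, 1.08e-29 for fibroblast, 3.28e-16 for Hox and 3.69e-09 for macrophage genes, and these calls held with an estimated correlation. The macrophage call ended without the doubted library (adjusted p = 0.186 with an estimated correlation).

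Signalling and glial genes moved as well. Interferon response genes fell in 12 of 16 cases (Isg15, log2 -8.31 ± 1.03; adjusted p = 3.53e-08), STAT3 targets in 8 of 10 (adjusted p = 6.58e-06) and epithelial genes in 7 of 20 (adjusted p = 0.0126). Of 10 astrocyte genes 8 rose (Aldoc, log2 9.22 ± 0.81; adjusted p = 2.86e-05), and 7 of 15 neuron genes rose with 2 falling (adjusted p = 0.023, and 0.0946 without the doubted library). None of these 5 calls held, with adjusted p = 0.187, 0.0765, 0.282, 0.178 and 0.398 with an estimated correlation. The STAT3 (adjusted p = 0.00101) and astrocyte calls (adjusted p = 0.0467) did pass with an estimated correlation once the doubted library was left out. Forebrain and midbrain genes went both ways, with 3 rising and 3 falling of 10 (adjusted p = 0.67). Their median was -0.12 and their mean 1.02 on the log2 scale, and the median turned to 0.0145 after another quantile normalization. ERK feedback genes also split, with 4 rising and 4 falling of 14 (median log2 0.65, mean -0.54, adjusted p = 0.492).

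The established lines were compared with primary NSCs to ask how far induced cells matched them. Olig2 stood at 14879.5 ± 1996 in iNSC_BKMF and 26505 ± 0 in iNSC_KF against 15651 ± 905 in NSCs, and Sox2 at 3254 ± 157 and 2446 ± 670.3 against 3448 ± 276 (n = 2). Without the doubted library 456 genes separated iNSC_BKMF from NSCs, and with all libraries 93 did (37 higher, 56 lower). They included Zfp300 (146 ± 7.78, listed at 0 in NSCs), Slitrk6 (506 ± 17.7 in NSCs, listed at 0 in the line) and Ccnb2 (log2 -1.76 ± 0.24; adjusted p = 0.0762 with the compared groups only). Skeletal muscle genes rose in 2 of 8 cases, Tnnt3 (24 ± 7.07) and Myh3 (21.5 ± 0.707), and both calls ended without any 1 of the 4 compared libraries (adjusted p = 0.0677 to 0.243). The line iNSC_KF differed at 708 genes (414 higher, 294 lower), at 1891 without the doubted library and at 422 with the compared groups only. Of 37 Hox genes 13 rose and none fell, with Hoxb3 at 1190.5 ± 104 against 11 ± 9.9 (log2 6.76 ± 1.05). With the compared groups only, Hoxb3 (adjusted p = 0.085) and Dusp4 (adjusted p = 0.361) were not called. ERK feedback genes rose in 6 of 14 cases, among them Dusp4 (log2 3.42 ± 0.48, but 1.86 without iNSC_KF replicate 2). In the same line the neural stem cell genes Sox1 (log2 -3.10 ± 0.54) and Nr2e1 (log2 -2.19 ± 0.32) and the neural gene Pou3f4 (log2 -2.87 ± 0.52) fell.

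The direct comparison of the lines gave 881 genes, 384 higher and 497 lower in iNSC_BKMF. ERK feedback genes fell in 9 of 14 cases and rose in none, and Hox genes fell in 12 of 37. Dusp4 (log2 -3.64 ± 0.48, but -2.07 without iNSC_KF replicate 2 and adjusted p = 0.259 with the compared groups only) and Hoxb3 (log2 -6.84 ± 1.05) were lower and Sox1 (log2 2.68 ± 0.54) higher in iNSC_BKMF. The ERK and Hox calls held with an estimated correlation in both comparisons of iNSC_KF (adjusted p = 2.12e-12 and 9.96e-15 against NSCs, 3.17e-16 and 7.43e-14 between the lines). The muscle call for iNSC_BKMF against NSCs (adjusted p = 0.00012) ended without the doubted library (adjusted p = 0.0692 with an estimated correlation). Skeletal muscle genes between the lines (2 of 8 higher in iNSC_BKMF; adjusted p = 0.00569, 0.0202 with an estimated correlation) were not called without the doubted library (adjusted p = 0.108). Astrocyte genes in iNSC_KF against NSCs (none called; median log2 -0.77; adjusted p = 0.0362) had adjusted p = 0.569 with an estimated correlation, but 0.0378 without the doubted library. Against NSCs, oligodendrocyte genes in iNSC_KF (1 of 7 fell; adjusted p = 0.0282, 0.137 without the doubted library) had adjusted p = 0.234 with an estimated correlation. Cell cycle genes in iNSC_BKMF (none called; median log2 -0.39; adjusted p = 0.00023) had adjusted p = 0.522 with an estimated correlation. Without the doubted library the 3 counts were 456 for iNSC_BKMF and 1891 for iNSC_KF against NSCs and 2249 between the lines. The count of 93 also moved to 143 without iNSC_BKMF replicate 1 and 152 without NSC replicate 2.

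Day 4 of all cocktails was compared with MEFs. The MEFs were kept in MEF medium without Dox and no group lacked the factors, so factors, infection, Dox and NSC medium are not separated in this comparison. Fibroblasts had taken on epithelial genes by then, as 16 of 20 epithelial genes rose, none fell and 4 were not called. Cdh1 averaged 585 against 1 ± 1.41 in MEFs (log2 7.09 ± 0.72) and Krt8 4833 against 81.5 ± 21.9 (log2 5.72 ± 0.62). Keratinocyte genes rose in 7 of 11 cases (Krt14, log2 7.14 ± 0.45). Of 28 fibroblast genes 13 fell and none rose, among them Acta2 (4096 against 44402 ± 0, log2 -3.79 ± 0.37) and Cnn1 (log2 -5.91 ± 0.62), while Col1a2 was not called (log2 -0.78 ± 0.42). The introduced factors followed the cocktails. At day 4 Sox17 reached 30318 ± 5392 in BKM_FNV and 9348 ± 185 in BKM_Sox17 and was listed at 0 in BKM_Sox2 (n = 2). Sox2 reached 2215 ± 557 in BKM_Sox2, and Pou3f4 29410 ± 0 in BKM_FNV but 26.5 ± 6.36 in K_FNV (n = 2). Nes was not called.

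In the test 2384 genes were called at day 4, 1382 higher and 1002 lower (8 libraries against 2), and 3758 without the doubted library. Epithelial (adjusted p = 1.02e-25), keratinocyte (2.08e-14), fibroblast (4.3e-11) and factor genes (4 of 5 rose; adjusted p = 1.1e-12) kept their calls with an estimated correlation and without the doubted library. Macrophage genes fell in 9 of 12 cases (adjusted p = 1.7e-13). Trophoblast genes rose in 3 of 9 and fell in 1 (adjusted p = 0.0165, 0.0908 without the doubted library). Senescence and p53 genes rose in 4 of 14 and fell in 1 (Mmp3, log2 2.61 ± 0.23; adjusted p = 0.00056), with a median of 0.42 and a mean of -0.09 on the log2 scale. Without the doubted library these 3 had adjusted p = 0.096, 0.128 and 0.227 with an estimated correlation. Neuron (6 of 15 rose; adjusted p = 3.31e-06) and neural crest and Schwann genes (4 of 10 rose; adjusted p = 0.0117, 0.0952 without the doubted library) had adjusted p = 0.0952 and 0.12 with an estimated correlation. The neuron call had adjusted p = 0.00651 with an estimated correlation once the doubted library was left out. Rescaling moved the median of all genes from -0.01 to 0.17 on the log2 scale in this comparison without turning any list named here, and gave 1702 genes higher and 777 lower.

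BKM_FNV at day 18 was compared with day 4 to ask what changed while Dox was on. Epithelial genes continued to rise and pluripotency genes rose, with 12 of 20 epithelial genes up and none down (Epcam 2858 ± 1279 against 45.5 ± 6.36, log2 5.84 ± 0.61), and 6 of 25 naive pluripotency genes up and none down. Pou5f1, the gene of Oct4, rose to 1302 ± 774 from 5.5 ± 4.95 (log2 7.48 ± 0.43), whereas Sox2 was not called and Cdh1 was called only without the doubted library (log2 2.63 ± 0.71, adjusted p = 0.00292). Cell cycle genes fell in 12 of 20 cases and rose in none (Mcm5, log2 -3.47 ± 0.43), and 10 of 28 fibroblast genes rose (Postn, log2 4.08 ± 0.98). Of the introduced factors, 3 fell with Dox still present: Sox17 to 4947 ± 1314 from 30318 ± 5392 (log2 -2.63 ± 0.26), Pou3f4 (log2 -3.31 ± 0.52) and Klf4 (log2 -2.60 ± 0.36). Myc (3405 ± 216 against 11916 ± 327) was not called with all libraries (log2 -1.81 ± 1.05, adjusted p = 0.378) but was without the doubted one (log2 -1.81 ± 0.19, adjusted p = 3.85e-09) and with the compared groups only (adjusted p = 0.00445). The count was 2113 (1080 higher, 1033 lower; 2 libraries against 2), 4776 without the doubted library and 4376 with the compared groups only. STAT3 targets (5 of 10 rose; Stat3, log2 1.43 ± 0.12; adjusted p = 2.58e-07) and factor genes (adjusted p = 0.000141) kept their calls with an estimated correlation and without the doubted library. Cell cycle (adjusted p = 8.37e-18), epithelial (1.67e-15), fibroblast (5.79e-09), naive (2.71e-05) and keratinocyte genes (5 of 11 rose; adjusted p = 2.06e-05) kept theirs with an estimated correlation only while the doubted library was in the fit. Without it they had adjusted p = 0.0971, 0.0971, 0.0971, 0.23 and 0.23 with an estimated correlation.

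**Figure D1:**
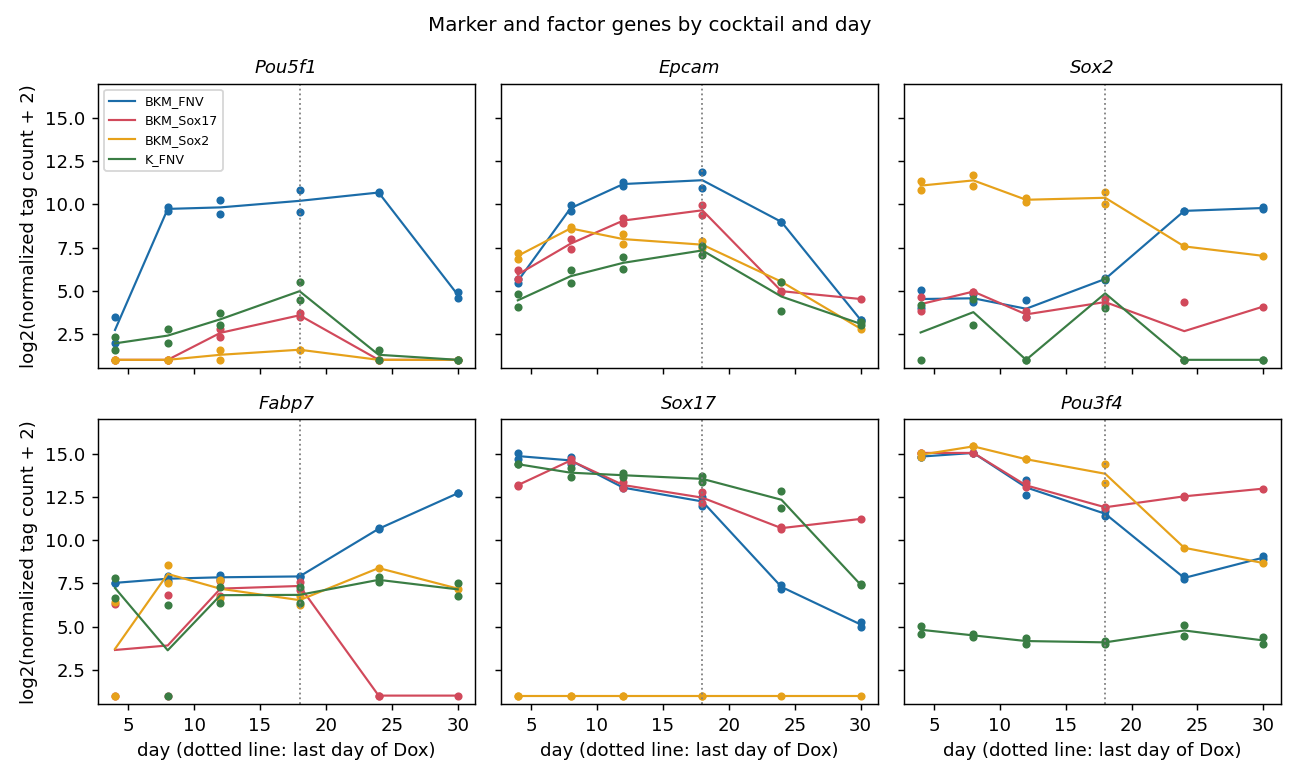
Normalized tag counts on the axis log2(value + 2) against day for 6 genes in the 4 NSC-medium cocktails, with dots for libraries, lines for group means and a dotted line at day 18, the last day with Dox. Pou5f1 is high in BKM_FNV from day 8 to day 24, and Sox2 and Fabp7 are high in BKM_FNV after Dox.

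eSox17FNV was compared with Sox17 on Dox, at days 4 to 18, to ask what the engineered variant changed. The cells with eSox17FNV expressed pluripotency genes: 11 of 25 naive pluripotency genes rose, 1 fell and 13 were not called, and 3 of 12 formative and primed genes rose and none fell. Pou5f1 averaged 777 against 3.5 (log2 6.09 ± 0.22, adjusted p = 8.38e-18), Lefty2 117 against 0.625 and Cldn6 238 against 23.9 (log2 2.77 ± 0.20), and the progenitor gene Nes was higher as well (log2 1.87 ± 0.47). Neuron genes went the other way, with 3 of 15 lower, such as Elavl3 (log2 -3.32 ± 0.33) and Neurog2 (log2 -2.51 ± 0.21). The factors themselves were not called over these days, with Sox17 at 17322 against 12444. At day 4 alone Sox17 stood well higher in BKM_FNV than in BKM_Sox17, as given above. A difference in the level of the introduced factor is therefore not separated from the change of protein. The count was 448 genes (292 higher, 156 lower in BKM_FNV; 8 libraries against 8), and 769 without the doubted library. The naive call (adjusted p = 1.64e-17) held with an estimated correlation and without the doubted library. The formative (adjusted p = 1.54e-06), epithelial (4 of 20 rose; adjusted p = 6.03e-07) and trophoblast calls (2 of 9 fell; adjusted p = 0.0142, 0.237 without the doubted library) did not. Without the doubted library they had adjusted p = 0.119, 0.326 and 0.326 with an estimated correlation. The neuron call (adjusted p = 0.000157, 0.0734 without the doubted library) had adjusted p = 0.268 with an estimated correlation.

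The variant was compared with Sox2 in the same way. Naive pluripotency genes rose in 13 of 25 cases and fell in 1, which was Sox2, the factor that BKM_Sox2 itself carried (27.1 against 1898, log2 -6.10 ± 0.38). Lefty2 (log2 4.35 ± 0.32), Lin28a (log2 2.79 ± 0.25), Nanog (201 against 62.2, log2 2.16 ± 0.44) and Nes (log2 2.04 ± 0.47) were higher in BKM_FNV. Endothelial genes, among which Sox17 and its relatives act in vessels, rose in 4 of 12 cases (Cdh5, log2 3.86 ± 0.30; Tie1, log2 2.06 ± 0.42), and 2 of 12 Wnt targets fell. Lor (69.9 against 1027, log2 -3.51 ± 0.32) and Lypd3 (log2 -3.24 ± 0.31) were lower in BKM_FNV, while the keratinocyte list went both ways (2 higher and 1 lower of 11; adjusted p = 0.44). The count was 902 genes (511 higher, 391 lower; 8 libraries against 8), and 1277 without the doubted library. The endothelial (adjusted p = 9.05e-07) and Wnt calls (adjusted p = 0.000147) held with an estimated correlation and without the doubted library. The naive call (adjusted p = 8.86e-11) and the formative call (3 of 12 rose; adjusted p = 7.68e-06) then had adjusted p = 0.0551 and 0.101 with an estimated correlation.

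K_FNV was compared with BKM_FNV on Dox to ask what Brn4 and c-Myc added. The cells of K_FNV were less epithelial, as all 20 epithelial genes were lower. Both factors were absent together, so their shares are not separated. Cldn4 averaged 18.4 against 2189.6 (log2 -6.52 ± 0.33) and Cdh1 357 against 1658 (log2 -2.15 ± 0.46). Naive pluripotency genes fell in 11 of 25 cases and rose in 1 (Sall4, log2 -3.59 ± 0.28), and formative and primed genes fell in 5 of 12. Fibroblast genes were higher in 10 of 28 cases (Thy1, 5329 against 884, log2 2.56 ± 0.21). So were 7 of 12 Wnt targets, with 1 lower (Axin2, log2 2.56 ± 0.37), and 4 of 12 endothelial genes (Kdr, log2 2.42 ± 0.12). Pou3f4 (19.5 against 18872) and Myc (1124 against 8156) were lower, the genes of both factors that K_FNV lacked. The count was 2359 genes (1241 higher, 1118 lower in K_FNV; 8 libraries against 8), and 3003 without the doubted library. The epithelial (adjusted p = 4.55e-28) and Wnt calls (adjusted p = 0.000249) held with an estimated correlation and without the doubted library. The fibroblast (adjusted p = 8.84e-08), naive (9.29e-06), formative (8.64e-05) and endothelial calls (0.000451) then had adjusted p = 0.0561, 0.172, 0.172 and 0.118 with an estimated correlation.

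Whether the course from day 4 to day 18 differed between cocktails was tested as an interaction. Against BKM_Sox17, Pou5f1 gained by a further log2 4.90 ± 0.61 in BKM_FNV (adjusted p = 6.64e-05). This call ended with the compared groups only (adjusted p = 0.0634) and with pseudocount 0.5 (log2 3.54, adjusted p = 0.113). Against BKM_Sox2, Epcam gained by a further log2 5.20 ± 0.87. Naive pluripotency genes were called higher in 2 of 25 cases against BKM_Sox17 (adjusted p = 1.87e-14) and epithelial genes in 2 of 20 (adjusted p = 4.01e-13). Without the doubted library these had adjusted p = 0.0503 and 0.127 with an estimated correlation. Against BKM_Sox2, naive pluripotency genes were called higher in 4 and lower in 1 of 25 cases (adjusted p = 1.88e-07, and 0.239 with an estimated correlation without the doubted library). Against BKM_Sox2, epithelial genes were called higher in 8 of 20 cases (adjusted p = 1.41e-37), a call that held with an estimated correlation and without the doubted library. The counts were 38 genes against BKM_Sox17 (26 higher, 12 lower) and 225 against BKM_Sox2 (123 higher, 102 lower; 4 libraries against 4 in each), and 443 (258 higher, 185 lower) and 1508 (743 higher, 765 lower) without the doubted library. They were 422 and 846 with the compared groups only and 22 and 147 with pseudocount 0.5, and the first was 62 with pseudocount 8. Leaving out 1 library moved the first count to 20 without BKM_FNV day 4 replicate 2 and 22 without BKM_FNV day 18 replicate 2. It moved to 23 without BKM_Sox17 day 18 replicate 1 or day 4 replicate 2 and to 24 without BKM_Sox17 day 4 replicate 1. The other count moved to 92 without BKM_FNV day 4 replicate 2 or BKM_Sox2 day 18 replicate 1 and to 96 and 121 without BKM_Sox2 day 4 replicates 1 and 2. It was 133 without BKM_FNV day 4 replicate 1, and 138 and 119 without BKM_FNV day 18 replicates 1 and 2.

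After Dox was withdrawn, the cocktails were compared at days 24 and 30 to ask which cells held a neural state. With eSox17FNV in place of Sox17, the cells expressed neural stem cell genes: 18 of 26 rose, none fell and 8 were not called. Fabp7 reached 6752 ± 0 in BKM_FNV at day 30 and was listed at 0 in BKM_Sox17. Sox2 averaged 838 against 12 (log2 6.34 ± 0.60), Pax6 403 against 5.25 (log2 6.71 ± 0.88) and Nes 5632 against 836 (log2 2.91 ± 0.74). Olig2 reached only 140 ± 24 at day 30, against 15651 ± 905 in NSCs. Pluripotency genes were higher too, with 17 of 25 naive genes up and 2 down and 8 of 12 formative and primed genes up. Pou5f1 was 1652 ± 43.8 at day 24 and 25.5 ± 4.95 at day 30 in BKM_FNV and listed at 0 in BKM_Sox17. Neuron genes rose in 9 of 15 cases and fell in 1, and Wnt targets rose in 6 of 12 and fell in 1 (Axin2, log2 4.71 ± 0.59). Cell cycle genes rose in 8 of 20 (Top2a, log2 2.31 ± 0.20), while senescence and p53 genes fell in 4 of 14 (Cdkn2a, log2 -1.64 ± 0.20). The factor genes other than Sox2 were all lower in BKM_FNV: Sox17 averaged 94.2 against 2036, Pou3f4 367 against 7053, Klf4 329 against 2771 and Myc 488 against 3230. The call of Myc ended without any 1 of the 6 compared libraries that have a replicate (adjusted p = 0.0517 to 0.0548), and with pseudocount 0.5 (adjusted p = 0.09).

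The count in this comparison was 2266 genes (1343 higher, 923 lower in BKM_FNV; 4 libraries against 3), and 3704 without the doubted library. The neural stem cell (adjusted p = 1.43e-28), naive (2.75e-13), formative (1.64e-11), neuron (4.36e-08), Wnt (1.32e-07), p53 (7.65e-08), skeletal muscle (5 of 8 rose; 0.00065) and factor gene calls (4 of 5 fell; 1.72e-05) held with an estimated correlation and without the doubted library. The cell cycle call (adjusted p = 4.58e-10) then had adjusted p = 0.0977 with an estimated correlation. The endoderm call (4 of 12 rose and 1 fell; adjusted p = 0.00799) had adjusted p = 0.107 with an estimated correlation.

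Against BKM_Sox2 after Dox the size of the difference rested on the doubted library, which is 1 of the 3 BKM_Sox2 libraries and has 18322 of its 21241 genes on a sequence of values that never falls along the rows of the file. With it 6694 genes were called (3695 higher, 2999 lower in BKM_FNV), without it 3150 (1809 higher, 1341 lower), and 2233 were called the same way in both. Without the doubted library BKM_Sox2 had only 1 library at day 24 and 1 at day 30, so the spread used came wholly from other groups. The direction depended on scaling, with 6146 higher and 2382 lower after rescaling and 3205 higher and 3904 lower after another quantile normalization. Leaving out BKM_Sox2 day 24 replicate 2 instead gave 14672, and a limma fit to the compared groups alone called 0 genes with 1314 at an unadjusted p under 0.05. Neural stem cell genes rose in 20 of 26 cases (16 up and 1 down without the doubted library) and naive pluripotency genes in 20 of 25 (21 up and 1 down). So did formative and primed genes in 8 of 12 (9 up) and neuron genes in 12 of 15 (11 up). Sox3 (log2 6.59 ± 0.53 with all libraries, 7.76 ± 0.17 without the doubted one), Tubb3 (6.12 ± 0.42 and 5.40 ± 0.31) and Lin28a (7.08 ± 0.40 and 7.63 ± 0.35) were higher in BKM_FNV either way. These 4 lists (adjusted p = 5.61e-11, 9.28e-13, 1.39e-05 and 8.78e-10) kept their calls with an estimated correlation and without the doubted library. The median of all genes moved from 0.41 to 0.59 on the log2 scale with rescaling and was -0.09 without the doubted library, so single genes in this comparison are not described further.

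K_FNV was compared with BKM_FNV after Dox in the same way. Neural stem cell genes were lower in K_FNV in 18 of 26 cases and higher in none, naive pluripotency genes in 20 of 25 with 2 higher. Formative and primed genes were lower in 9 of 12 and neuron genes in 11 of 15. Sox2 and Sox3 were both listed at 0 in K_FNV, against 838 and 1154 in BKM_FNV, and Lin28a fell from 865 to 1. Cell cycle genes were lower in 14 of 20 cases (Top2a, log2 -3.40 ± 0.17). Senescence and p53 genes, which arrested fibroblasts express, were higher in 7 of 14 and lower in none (Mmp3, 34134 against 1349.8; Cdkn2a, log2 2.27 ± 0.18). Interferon response genes were higher in 13 of 16 cases (Isg15, log2 3.56 ± 0.73; adjusted p = 0.0854 with the compared groups only) and endothelial genes in 6 of 12 with 1 lower (Tie1, log2 5.47 ± 0.59). The count was 3176 genes (1576 higher, 1600 lower in K_FNV; 4 libraries against 4), and 4543 without the doubted library. The neural stem cell (adjusted p = 6.03e-24), naive (2.89e-17), formative (1.6e-13), neuron (4.89e-11) and p53 calls (5.6e-12) held with an estimated correlation and without the doubted library. The cell cycle (adjusted p = 3.93e-17) and endothelial calls (0.0032) then had adjusted p = 0.0602 and 0.197 with an estimated correlation, and the interferon call (adjusted p = 3.97e-08) had adjusted p = 0.12 with an estimated correlation. Adjusted over the list alone, the counts here were 21 of 26 neural stem cell genes lower, 15 of 20 cell cycle genes lower, 8 of 14 p53 genes higher and 15 of 16 interferon genes higher.

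Positions between MEFs (0) and NSCs (1) summarised 2378 genes to gain and 2551 to lose. On Dox the cocktails had moved little: BKM_FNV at day 18 stood at 0.2 ± 0.00122 for gain and 0.13 ± 0.000293 for loss (n = 2). The gain of BKM_FNV had been 0.23 at day 12 and its loss 0.212 at day 4. In the other cocktails, too, loss was lower at day 18 than at day 4, and so closer to MEFs. After Dox, BKM_FNV moved to a gain of 0.327 ± 0.00185 at day 24 and 0.578 ± 0.00594 at day 30, with a loss of 0.426 ± 0.00112 at day 30. The day 30 gain was 0.219 in BKM_Sox17, 0.253 in BKM_Sox2 and 0.188 ± 0.00129 in K_FNV. The lines iNSC_BKMF and iNSC_KF stood at 1.02 ± 9.9e-05 and 0.934 ± 0.0405. By exact permutation within days on Dox, gain was higher in BKM_FNV than in BKM_Sox2 by 0.0616 (p = 0.00154, the smallest the 1296 arrangements can give, adjusted p = 0.00309). K_FNV minus BKM_FNV was -0.0549 in gain and -0.0825 in loss (each exact p = 0.00154, adjusted p = 0.00309). With genes of a log2 threshold of 3 that gain was -0.0214 (exact p = 0.106). Loss was higher in BKM_FNV than in BKM_Sox17 by 0.015 (exact p = 0.00463, adjusted p = 0.00694), but only by 0.00408 after rescaling (exact p = 0.375). The gain of BKM_FNV over BKM_Sox17 (0.0248, exact p = 0.0509, adjusted p = 0.0611) and the loss against BKM_Sox2 (0.00856, exact p = 0.091) did not pass. Leaving out 1 library, or another setting, could bring either under an exact p of 0.05 before adjustment. At day 8 the gain was lower in BKM_FNV (0.152) than in BKM_Sox17 (0.17). After Dox the design could not reach 0.05, the smallest exact p being 0.0556. The gain of BKM_FNV exceeded that of BKM_Sox17 by 0.246 and of BKM_Sox2 by 0.212, and K_FNV minus BKM_FNV was -0.277, each at this exact p of 0.0556. The difference from BKM_Sox2 includes the doubted library, with a gain of 0.15 where its replicate stood at 0.307, close to the 0.327 of BKM_FNV at day 24. The loss against BKM_Sox2 after Dox went the other way (-0.0695, exact p = 0.889), with the doubted library at a loss of 0.798 and its replicate at 0.223.

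**Figure D2:**
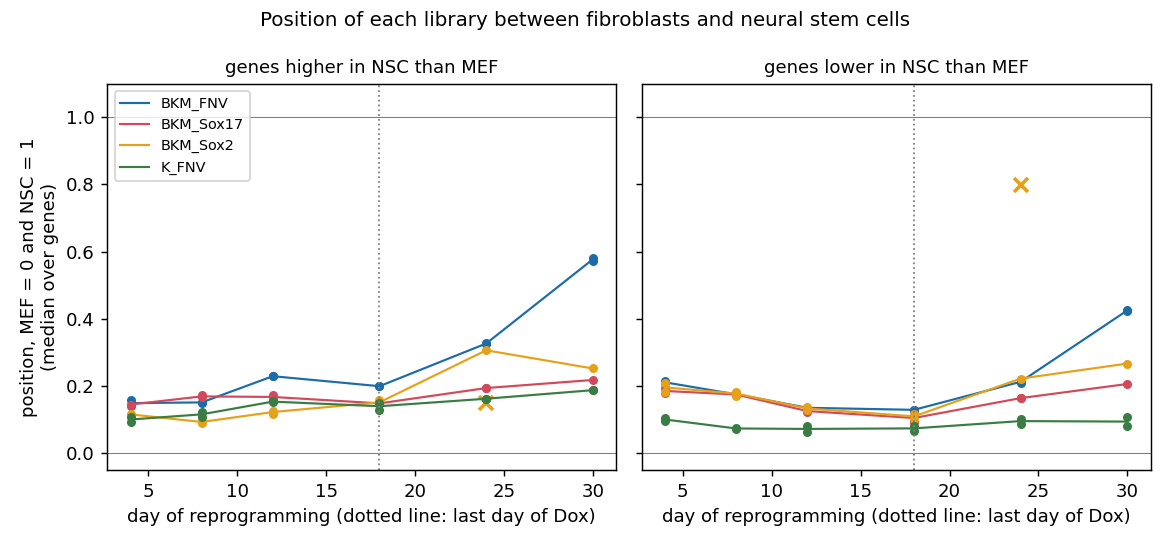
Position of each library between MEFs (0) and NSCs (1), without unit, against day for genes gained and genes lost, with dots for libraries, lines for group means and a dotted line at day 18. BKM_FNV reaches a gain of 0.578 at day 30, and the cross marks BKM_Sox2 day 24 replicate 1, which is left out of the line.

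**Figure D3:**
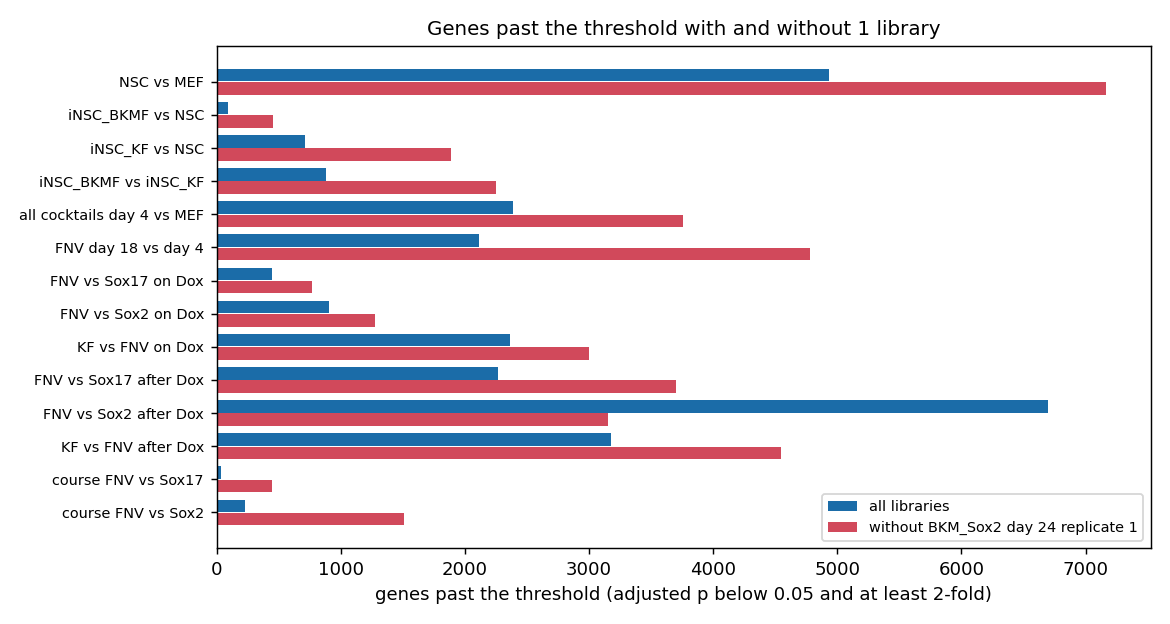
Bars count the genes past both thresholds in 14 comparisons of the NSC-medium table, with all libraries and without BKM_Sox2 day 24 replicate 1, on an axis of number of genes. The count falls in the comparison of BKM_FNV with BKM_Sox2 after Dox, from 6694 to 3150, and is higher without that library in each of the other 13.

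The parallel experiment asked how the same cells respond to a neural or a pluripotency medium, and began with 8 days in N2B27. From day 4 to day 8 naive pluripotency and epithelial genes rose, with 18 of 26 naive genes up and none down and 13 of 20 epithelial genes up and none down. Pou5f1 rose to 2662 ± 1867 from 608 ± 36.1 (log2 1.93 ± 0.45) and Epcam to 678 ± 18.4 from 12.5 ± 3.54 (log2 5.57 ± 0.41). Sox2 rose to 97.5 ± 34.6 from 5.5 ± 7.78 (log2 4.24 ± 0.55), while Nanog was not called. With the compared groups only, Sox2 (adjusted p = 0.205) and Pou5f1 (adjusted p = 0.248) were not called. The call of Pou5f1 ended without day 4 replicate 1 (adjusted p = 0.0801), day 4 replicate 2 (0.0589) or day 8 replicate 1 (log2 1.14, adjusted p = 0.115). Trophoblast genes rose in 5 of 11 cases (Prl2c2, log2 5.76 ± 0.12) and ERK feedback genes in 5 of 14 (Etv5, log2 1.95 ± 0.13). The count was 964 genes (614 higher, 350 lower; 2 libraries against 2), but 629 without day 4 replicate 1, 544 without day 8 replicate 2 and 294 with the compared groups only. After rescaling 773 were higher and 218 lower. The naive (adjusted p = 2.13e-20), epithelial (2.46e-18), trophoblast (2.09e-06) and ERK calls (2.16e-10) held with an estimated correlation. The formative call (6 of 12 rose; adjusted p = 7.63e-07) had adjusted p = 0.071 with an estimated correlation.

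In NSC medium, days 20 and 24 were compared with day 8. Cells of day 8 were in N2B27 with Dox, so medium, Dox and day are not separated here, nor in the same comparison for LIF/2i. Keratinocyte genes fell in 10 of 11 cases and rose in none (Krt5, 6.25 against 814, log2 -6.95 ± 0.52), and the introduced Sox17 fell (log2 -5.99 ± 0.35). ERK feedback genes, which FGF and EGF can induce, rose in 11 of 14 cases and fell in 1 (Spry2, 6113 against 688, log2 3.05 ± 0.07). Formative and primed genes rose in 10 of 12 (Otx2, log2 3.35 ± 0.65; Lefty1, log2 4.13 ± 0.49). Nanog rose (log2 1.16 ± 0.22) and Sox2 rose (log2 1.81 ± 0.47), while Pou5f1 was not called. All 3 rested on single libraries. Without day 24 replicate 2 of NSC medium or day 8 replicate 2, Nanog came to log2 0.91 and 0.93, under the threshold, and Pou5f1 was called at -1.26 and -1.61. Without day 8 replicate 1 the call of Sox2 ended (log2 1.44, adjusted p = 0.117), as it did with pseudocount 0.5 (adjusted p = 0.0813), and that of Nanog ended with the compared groups only (adjusted p = 0.111). In LIF/2i, 25 of 26 naive genes rose and none fell: Nanog went to 12052 from 232 (log2 5.67 ± 0.22), Dppa5a to 42201 from 138 and Sox2 by log2 4.87 ± 0.47. Zscan4c, of a gene cluster transcribed in bursts in embryonic stem cells, stood at 5503 against 1.5, and 13 of 28 fibroblast genes fell and none rose (Acta2, log2 -3.25 ± 0.26). The counts were 2852 genes in NSC medium (1472 higher, 1380 lower) and 4847 in LIF/2i (2372 higher, 2475 lower; 4 libraries against 2 in each). The keratinocyte call in NSC medium (adjusted p = 1.33e-09) and the fibroblast call in LIF/2i (adjusted p = 3.25e-05) held with an estimated correlation. The ERK (adjusted p = 3.38e-10) and formative calls (6.83e-06) in NSC medium had adjusted p = 0.0614 and 0.128 with an estimated correlation. The naive call in LIF/2i (adjusted p = 5.68e-14) had adjusted p = 0.0672 with an estimated correlation. In LIF/2i the median of all genes was -0.11 on the log2 scale, and -0.06 after rescaling.

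Both media were compared directly at days 12 and 16 on Dox and at days 20 and 24 after it. On Dox, LIF/2i already held 22 of 26 naive genes higher and none lower, with Esrrb at 2407 against 162 (log2 4.45 ± 0.35) and Nanog at 3884 against 537 (log2 2.94 ± 0.18). ERK feedback genes were lower in 12 of 14 cases (Dusp4, log2 -4.65 ± 0.22) and Wnt targets higher in 10 of 13 (Axin2, log2 4.95 ± 0.43), the directions in which the MEK and the GSK3 inhibitor act. The inhibitors are not separated from the other differences between the media, such as the bFGF and EGF of NSC medium. After Dox 22 of 26 naive genes were higher and none lower (Tfcp2l1, log2 5.62 ± 0.24), and Pou5f1 averaged 8916 against 1444. ERK feedback genes were lower in 13 of 14 cases and higher in 1 (Dusp6, log2 -4.18 ± 0.14) and 9 of 13 Wnt targets were higher. Fibroblast genes were lower in 14 of 28 (Col6a1, log2 -1.98 ± 0.17). Nes was lower in LIF/2i (log2 -1.95 ± 0.09). Olig2 was higher in LIF/2i (104 against 31, log2 3.02 ± 0.51), although the libraries of both media overlapped at a day compared, and stayed far under the 18668 ± 1351 of NSCs in this table.

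The counts were 3175 genes on Dox (1650 higher, 1525 lower in LIF/2i) and 5016 after it (2507 higher, 2509 lower; 4 libraries against 4 in each). The fibroblast call after Dox (adjusted p = 1.74e-05) held with an estimated correlation. On Dox the naive (adjusted p = 3.09e-13), ERK (4.8e-11) and Wnt calls (7.3e-06) had adjusted p = 0.0555, 0.0502 and 0.0502 with an estimated correlation. After Dox the naive (adjusted p = 1.86e-10), ERK (1.66e-07) and Wnt calls (0.000148) had adjusted p = 0.107, 0.107 and 0.107 with an estimated correlation. Whether the effect of the medium differed between the days on Dox and the later days after it was tested as an interaction. It called 2838 genes (1332 higher and 1506 lower, 8 libraries against 8), and Dox is not separated from the day in it. The gap between the media widened for Nanog (log2 1.57 ± 0.25), and Col1a1 moved down by log2 -2.10 ± 0.24. Fibroblast genes were lower in 8 of 28 cases and higher in 1, a call (adjusted p = 0.00103) that held at adjusted p = 0.0492 with an estimated correlation.

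**Figure D4:**
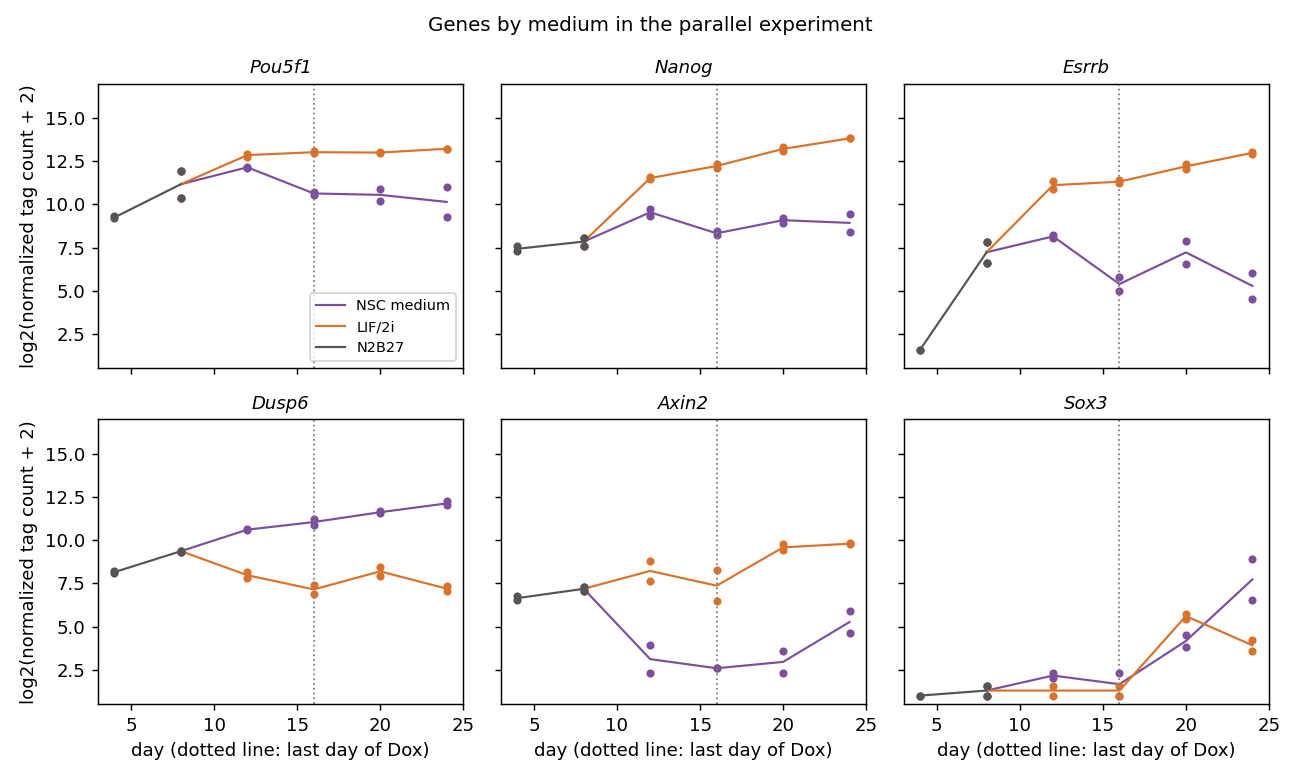
Normalized tag counts on the axis log2(value + 2) against day for 6 genes in N2B27, NSC medium and LIF/2i, with dots for libraries, lines for group means and a dotted line at day 16, the last day with Dox. Nanog, Esrrb and Axin2 are higher and Dusp6 is lower in LIF/2i than in NSC medium.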

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

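All tests of explanations and of other splits of the libraries in this part were chosen after the results they concern had been seen. The 3 contrasts that tested a difference between groups directly found such differences. Between days 4 and 18 the change in BKM_FNV differed from that in BKM_Sox17 at 38 genes, with Pou5f1 gaining a further 4.90 on the log2 scale, and from that in BKM_Sox2 at 225 genes, with Epcam gaining a further 5.20. The Pou5f1 difference had an adjusted p of 0.0634 with a fit to the compared groups only and of 0.113 with pseudocount 0.5 (log2 3.54), and it ran from 8.44e-09 to 0.113 over all alternatives. The effect of LIF/2i against NSC medium after Dox differed from that on Dox at 2838 genes, with Nanog at 1.57 and Col1a1 at -2.10.

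Fits to the compared libraries alone, with the day as a term and for interactions also the cocktail or medium, were repeated over other splits of the same libraries. Most other splits part libraries of the same group, so they show only whether the real grouping stands out among these libraries. They cannot exclude chance differences between cultures, as the labels do not say whether replicates were separate cultures. No other split reached the real count for the course of BKM_FNV against BKM_Sox17 (1 of 33 splits, 423 genes against 12 in the highest other). The same held for the course against BKM_Sox2 (1 of 33, 848 genes against 13). For the comparisons on Dox, 100 of 6435 possible splits were run. No other split reached the real count for BKM_FNV against BKM_Sox17 (1 of 100, 582 genes against 242) or BKM_FNV against BKM_Sox2 (1 of 100, 1029 against 267). The same held for K_FNV against BKM_FNV (1 of 100, 2766 against 1653). The last of these highest splits differs from the real one only by exchanging BKM_FNV day 4 with K_FNV day 8. After Dox no other split reached the real count for BKM_FNV against BKM_Sox17 (1 of 34, 2359 against 158) or K_FNV against BKM_FNV (1 of 34, 3600 against 15). In the parallel experiment none did for the media on Dox (1 of 34, 2290 against 16) or after it (1 of 34, 4661 against 11). For the change in the effect of the medium, where this form of fit calls 2091 genes and one with a mean per group 2861, 1 of 100 splits gave as many as 2091, and the highest other, 2030, differed from the real split by exchanging 1 pair of LIF/2i libraries. For BKM_FNV against BKM_Sox2 after Dox the splits decide nothing, because limma called 0 genes in the real split, with 1314 at an unadjusted p under 0.05, so that 34 of 34 splits gave as many. The highest other split there, with 15004 genes, points to a structure of the samples, since it sets BKM_Sox2 day 24 replicate 1 apart from the day's other libraries.

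BKM_Sox2 day 24 replicate 1 was unlike every other library, with a correlation of 0.0578 with its replicate where other replicate pairs had at least 0.949. An exchange with another library of the table is argued against as the whole cause by its highest correlation with any of them, 0.0865, and a trend with GC content, although its medians fell from 150 to 7 between the bins of lowest and highest GC content, is argued against as the whole cause by its correlation with its replicate after medians were equalised by GC content, 0.0814. A loss of usable reads before the authors' normalization may be a candidate explanation, since genes without reads are tied and a quantile normalization can rank ties by row: 18322 of its 21241 genes lie on 1 sequence of values that never falls along the rows of the file, against at most 4569 in any other library, which also argues against a sample of other material as the whole cause. A loss alone would keep the order of abundance, yet the medians in the 3 bins of genes least abundant elsewhere were 115, 197 and 97 (0, 7 and 23 in its replicate) and in bins with 446 to 1343 there they were 4 to 10, as the former genes stand later in the file (median rows of 14707 to 16341 against 7206.5 to 7955.5), while its 2919 genes off the sequence, at 1418 or more, had a correlation of 0.482 with its replicate and at most 0.463 with another library. Few reads cannot be told apart from a fault in counting that left most genes equal, because the deposited values hold no read numbers, and no biological explanation was tested, as the design gives the library no group of its own.

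After Dox, genes of the introduced factors stayed high in BKM_Sox17 and, at day 24, in K_FNV, with Sox17 at 1621 to 2408 in the 3 BKM_Sox17 libraries against 30 to 167 in the 4 BKM_FNV libraries. A single library is argued against by the lowest BKM_Sox17 value of 1621, above the highest BKM_FNV value of 167, and in K_FNV by the value of 3716 in the second-highest library, although the K_FNV libraries of day 30 stood only at 174 and 167. Continued expression from the delivered copies may be a candidate explanation, since K_FNV, which lacked them, had Pou3f4 at no more than 32 and Myc at 493 to 734, under the 33 and 1743 of fibroblasts, and BKM_Sox17, without Sox2, had Sox2 at up to 18 where fibroblasts had 0. Endoderm cells, which express Sox17, cannot be told apart from this for Sox17 in BKM_Sox17, because endoderm genes went both ways (median log2 -1.12, 4 of 12 lower and 1, Gata6, higher). The values do not separate delivered from endogenous transcripts, as Myc in K_FNV lay above the 391 to 582 of BKM_FNV, which carried c-Myc, and Sox2 stood at 789 to 930 in BKM_FNV, which lacked it, and silencing of the lentiviral copies by the cell state, a biological difference between the cocktails, was not tested.

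Pluripotency genes appeared in BKM_FNV in NSC medium, with Pou5f1 at 687 to 1850 in the 8 libraries of days 8 to 24 and at most 43 in the 34 libraries of the other cocktails. A single library is argued against by the lowest of those 8 values, 687. RNA from the LIF/2i cultures would bring every gene abundant there. Of 11 such naive genes, 4 (Esrrb, Dppa3, Dppa5a and Zfp296) had ratios to Pou5f1 below those of all 8 LIF/2i libraries. Esrrb stood at 0.0053 to 0.0296 against at least 0.237, Dppa5a at up to 0.425 against 1.07, and Zfp296, the closest, at up to 0.122 against 0.131. These 4 genes argue against such RNA as the whole source of Pou5f1 in these 8 libraries. The ranges of the other 7 overlapped, and a smaller share of such RNA cannot be told apart from expression in these cells. Of 2 earlier forms of this test, the first gave levels of 0.0433 to 1.43 times those this source would need (median 0.412) and decided nothing, and the other used Dppa5a alone, the gene that had differed most, and was dropped for that reason. An effect of eSox17FNV, which the design names, stays open, and whether all cells or a few carried the RNA was not tested.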

How the results depend on the processing

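Leaving the doubted library, BKM_Sox2 day 24 replicate 1, out of every fit was chosen after the data were seen, and the other alternatives were planned. Of 26 comparisons and positions, all 26 kept their direction and side of the threshold, or a count within 1.5 times, with no filter and with a value of at least 50, 25 with another quantile normalization, 24 with rescaling and with pseudocount 8, and 23 with pseudocount 0.5. All 20 counts stayed within 1.5 times with the replicate block (for example 443 genes for BKM_FNV against BKM_Sox17 on Dox), and 14 of 20 with the compared groups only. Without the doubted library 9 of 20 results stayed, 10 counts moved and 1 position came under an exact p of 0.05. Throughout this part the threshold of 0.05 for positions applies to the exact p without adjustment, unlike in the methods above.

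Without the doubted library the counts were 456 for iNSC_BKMF against NSCs, 1891 for iNSC_KF against NSCs, 2249 between the lines, 3758 for day 4 against MEFs, 4776 for BKM_FNV day 18 against day 4, 769 for BKM_FNV against BKM_Sox17 on Dox and 3704 after it, 3150 for BKM_FNV against BKM_Sox2 after Dox, and 443 and 1508 for the courses against BKM_Sox17 and BKM_Sox2. With the compared groups only they were 422 for iNSC_KF against NSCs, 4376 for day 18 against day 4, 422 and 846 for both courses, 294 for parallel day 8 against day 4, and 0 for BKM_FNV against BKM_Sox2 after Dox (limma, 1314 at an unadjusted p under 0.05). Pseudocount 0.5 gave 22 and 147 for both courses and pseudocount 8 gave 62 for the first. In the NSC-medium table a fit to the compared groups also leaves out the doubted library, except for BKM_FNV against BKM_Sox2 after Dox, so that 2 choices change at once and their shares in these moves were not separated. The causes of the other moves were not tested.

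The gain of BKM_FNV over BKM_Sox17 on Dox passed an exact p of 0.05, without adjustment, in several settings. It is an average over days that did not agree. In the main setting BKM_FNV stood lower at day 8 (0.152 against 0.17) and about level at day 4 (0.15 against 0.145). It was higher at day 12 (0.23 against 0.168) and day 18 (0.2 against 0.149). The averaged difference was 0.0342 with pseudocount 0.5 (exact p = 0.0231) and 0.0254 with pseudocount 8 (exact p = 0.0401). With rescaling it was 0.0385 (exact p = 0.0185), and with another quantile normalization 0.0258 (exact p = 0.0401). A log2 threshold of 3 gave 0.0316 (exact p = 0.0185) and the limited mean 0.0221 (exact p = 0.0309). Without the doubted library the difference was 0.0275 (exact p = 0.0478). The loss difference from BKM_Sox17 was 0.00408 with rescaling and no longer passed (exact p = 0.375). Nor did the gain difference of K_FNV from BKM_FNV, -0.0214 with a log2 threshold of 3 (exact p = 0.106). The loss difference from BKM_Sox2 was 0.0202 with the limited mean and passed (exact p = 0.00154). The causes of these moves were not tested.

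Leaving out 1 library moved 18 counts by more than 1.5 times and brought 10 position tests under 0.05, out of 258. A group left with 1 library was assumed to vary like the others. The ranges were 109 to 152 for iNSC_BKMF against NSCs, 3150 to 14672 for BKM_FNV against BKM_Sox2 after Dox, 20 to 50 and 92 to 260 for the courses, 544 to 1194 for parallel day 8 against day 4, 0.0227 to 0.0269 for the gain of BKM_FNV over BKM_Sox17 and 0.00514 to 0.012 for its loss over BKM_Sox2.

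Of 134 gene results followed, 134 kept call and direction with no filter and with the replicate block, 132 with pseudocount 8, 131 with rescaling and with another quantile normalization, 130 with pseudocount 0.5 and 118 with the compared groups only. With a value of at least 50 all 132 did, without the doubted library 98 of 100, and with 1 library left out 1046 of 1074. In iNSC_BKMF against NSCs, Sox2 reversed at 4.76e-05 without NSC replicate 2 and stood at -0.16 without NSC replicate 1, and Olig2 reversed at 0.0590 without iNSC_BKMF replicate 1 and stood at -0.22 without replicate 2; neither was called. A method for raw counts was not run, as the values are not raw counts.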

Other observations

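Several gene groups moved in comparisons where the report does not describe them. In the parallel experiment, proliferation genes were higher in LIF/2i than in NSC medium after Dox, with 16 of 20 cell cycle genes up and none down (adjusted p = 2.16e-09; adjusted p = 0.169 with an estimated correlation). Interferon response genes were lower in 10 of 16 cases (adjusted p = 0.0357; adjusted p = 0.736 with an estimated correlation) and Hox genes lower in 17 of 34 and higher in 1 (adjusted p = 0.00691; adjusted p = 0.169 with an estimated correlation). On Dox, endothelial genes were lower in LIF/2i in 6 of 12 cases and higher in 1 (Cdh5, log2 -4.19 ± 0.43; adjusted p = 0.00346; adjusted p = 0.0502 with an estimated correlation). The imprinted gene Peg10, which the placenta needs, rose between days 4 and 8 in N2B27 (log2 3.44 ± 0.43; adjusted p = 0.138 with the compared groups only).

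In NSC medium, the iron-binding protein gene Lcn2 stood among the largest increases of BKM_FNV between days 4 and 18 (3866 ± 214 against 3.5 ± 2.12, n = 2, log2 9.51 ± 0.97), beside the basement membrane collagen gene Col15a1 (log2 8.89 ± 0.81). The cartilage collagen gene Col2a1 was higher in BKM_FNV than in BKM_Sox17 after Dox (2224 against 1). In K_FNV after Dox, Hox genes were higher than in BKM_FNV in 15 of 37 cases and lower in 2 (adjusted p = 0.00448; adjusted p = 0.392 with an estimated correlation). Tex12, a gene of the meiotic synaptonemal complex, was listed at 0 in NSCs and stood at 405 ± 17 in iNSC_BKMF (n = 2).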
